A study of Homo sapiens with 8 samples.

How the data were processed

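MicroRNAs (miRNAs) were measured in 3 established human breast cancer cell lines, HCC70, HCC1954 and MCF-7, which carried a luciferase gene per the labels. Total RNA, 100 ng per sample, was labelled with Cy3 and hybridised to 8 one-colour Agilent human miRNA arrays on 1 slide, read in 1 scan. Adherent cells grew in medium with 10% serum. Mammospheres, here called spheres, grew from single cells in serum-free medium with growth factors. The RNA came from phenol-based extraction per the labels' protocols.

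The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made with Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5.3.1. The processed intensity of a spot is background-subtracted, per the file headers. Each array had 15024 spots that were not controls, for 851 human and 88 viral miRNAs with 1 to 4 probes each, and 0 spots were saturated. Flags for spots well above background, also deposited per the file headers, marked detection.

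The deposited table of the authors' processed values holds a linear ratio of each miRNA's signal to 1 number per array, without centring; how the table was made is not given in the sources used here. Over the HCC1954 columns, 202, 207 and 95 of as many detected rows equalled the scanner's total miRNA signal times 1 factor, within 2%. That factor was the inverse of the array's 90th percentile over all rows. For the tumor sphere this percentile was 0.1, the value written for undetected miRNAs. In the table, the columns named for MCF-7 adherent cells and spheres held the HCC70 scanner values instead (229 of 229 and 169 of 169 rows within 2%). The HCC70 columns followed none of the scanner files row by row, with rank correlations between -0.27 and -0.11, so their row order, and with it their scale, stays unknown. Column medians of the table were 0.001, 0.004 and 0.004 for HCC70 adherent, sphere and taxol sphere, 0.003, 0.002 and 1 for HCC1954 adherent, sphere and tumor sphere, and 0.001 and 0.004 for MCF-7 adherent and sphere. Matched by rank alone, the 80 largest values of each HCC70 column lay closest to the HCC70 scanner file of the same name (SD of the log2 ratio 0.0988, 0.121 and 0.105). No column of the table held the MCF-7 scanner values. The scanner files and their labels were therefore used throughout, and the table served as an alternative for HCC1954. The sources do not settle whether the table or the scanner files carry the right MCF-7 label, and this doubt bears on every value given for HCC70 and MCF-7. A marker tied to estrogen receptor-positive tumors, hsa-miR-342-3p, was higher by 6.12 (log2) on the scanner arrays labelled MCF-7 than on the others. MCF-7 is the estrogen receptor-positive line, so this marker goes with the scanner labels.

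Control spots and spots flagged as outliers were left out. Processed signals were averaged per probe and summed over the probes of a miRNA. A probe counted as detected when at least 50% of its spots were well above background, and a miRNA when any of its probes did. Each array was divided by its 75th percentile over the 56 human miRNAs detected on all 8 arrays. Scaled signals were then raised to a floor of 0.0140, the 5th percentile of detected signals, and log2 was taken, so that the floor lies at -6.16. A miRNA entered the tests when it was detected on at least 3 of the 6 adherent and sphere arrays, which left 168. Of the listed miRNAs, hsa-miR-106a and hsa-miR-210* were not analysed here. Names are those of the array's design and partly old.

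Spheres were compared with adherent cells by limma 3.58.1 (R 4.3.3; lmFit and eBayes) over 6 arrays, with the cell line as a block and Benjamini-Hochberg adjustment. The pairing comes from the cell line labels. Deviations from the culture means correlated between the arrays of a line with r = 0.710 for HCC70, 0.816 for HCC1954 and 0.890 for MCF-7, across miRNAs. The residual degrees of freedom were 2 and the prior ones 2.70, and the median residual SD was 0.302 on the log2 scale. Cell lines were compared in the same fit, by an F test and then each line against the mean of the others. Lists of related miRNAs were tested with camera (preset correlation 0.01), and beside it with an estimated correlation and with fry. Comparisons of 1 array with 1 array had no test. For these, miRNAs detected on both arrays were counted at a log2 difference of at least 1 in size. List medians were placed among 10000 random lists matched on mean signal. Random lists hold miRNAs drawn independently, whereas members of a list can move together, so the percentiles are descriptive. The error given for these comparisons is the standard error over spots, which is technical only. A miRNA not well above background on every array of a group has only a bound there. It is the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the miRNA's own. Where the text gives "at least" a fold, it is this bound. It uses signals before the floor, and the lowest detected signal of an array can lie under the floor, so the bound can exceed the fold of the values in the fit.

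The following were fixed before the data were examined: the 15 lists, hsa-miR-27a as the miRNA of interest, the tests and the rule for named miRNAs. The title and description of the series single out hsa-miR-27a, so that choice is not independent of the data. The rule took up to 15 miRNAs per direction past an adjusted p of 0.05. Where fewer than 10 passed, the list was filled to 10 with miRNAs of 1 sign in all 3 lines and detected on all 6 arrays. To these it added the 3 tested members of each list with the largest difference. For the cell lines it took up to 8 miRNAs above and 4 below per line. For comparisons of 1 array with 1 array it took hsa-miR-27a, the 10 largest differences per direction, up to 5 per direction detected on 1 array, and list members that differed by at least 1. The text prints those that matter most.

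The alternatives covered the scaling, the background correction, the signal per miRNA, the floor, the detection filter, the variance model, the block and leaving out each line. The planned normexp correction used the median spot signal, because the mean signal is not among the columns used here. The fit was tested in 50 simulations of the 168 miRNAs, with changes added to fitted values. Normal noise was drawn with variances from the fit's own prior, and no floor was applied. The rates thus hold for that model and not for values at the floor. It recovered 34.4% of changes of 1, 70.0% of changes of 1.5, 85.2% of changes of 2 and 97.6% of changes of 4 on the log2 scale, and 5.14% of its calls were false. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Human miRNA genes were placed next to each other with RefSeq names of assembly GRCh38.p14, used for neighbourhood alone.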

Results

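The miRNA content of 3 breast cancer cell lines was compared between adherent culture and mammospheres, suspension spheres in which breast cancer stem cells are more frequent, with hsa-miR-27a as the miRNA of interest. HCC70 derives from a triple-negative carcinoma, HCC1954 from an HER2-positive one and MCF-7 from an estrogen receptor-positive one. Each line gave 1 adherent and 1 sphere array without a replicate within the line, with spheres taken at day 7 for HCC70 and day 6 for the others. The p-values for spheres measure how the sphere difference varies between lines, beside a prior drawn from all tested miRNAs. HCC70 also gave spheres at day 7 with 10 nM taxol, a microtubule-stabilising drug, and HCC1954 gave a primary sphere culture from a tumor.

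The arrays differed in miRNA signal. Detected human miRNAs numbered 193, 123 and 139 of 851 for HCC70 adherent cells, spheres and taxol spheres, 151, 166 and 68 for HCC1954 adherent cells, spheres and the tumor sphere, and 191 and 138 for MCF-7 adherent cells and spheres. Before scaling, the 75th percentile of signal was 2225 and 3115 on the HCC70 and MCF-7 adherent arrays and 773 and 1082 on their sphere arrays, whereas in HCC1954 it was 864 in adherent cells, 1217 in spheres and 124 in the tumor sphere. The mean log2 signal of 4 spike-in controls lay between 10.35 and 10.75 on all 8 arrays. The number of arrays limits the precision of all values below.

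**Figure D1:**
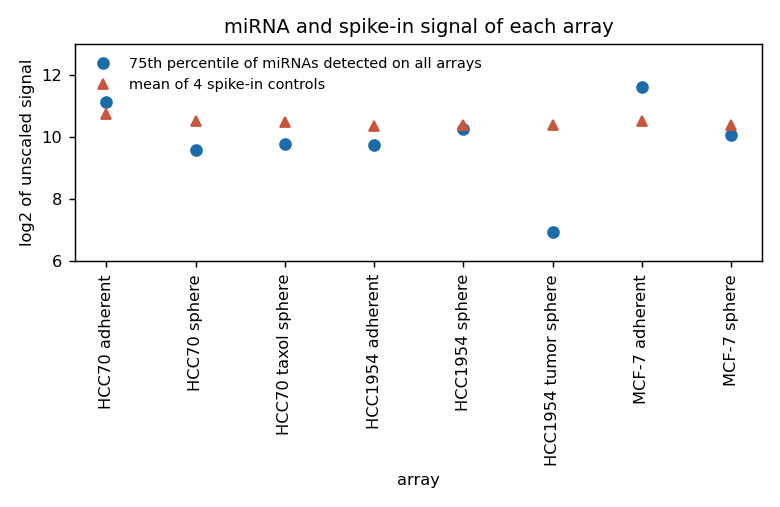
Unscaled signal (log2, vertical axis) of each of the 8 arrays (horizontal axis), with circles for the 75th percentile over miRNAs detected on all arrays and triangles for the mean of 4 spike-in controls. The spike-ins stay between 10.35 and 10.75 while the percentile ranges from 6.96 on the tumor sphere array to 11.60 on the MCF-7 adherent array.

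The miRNA of interest, hsa-miR-27a, which is made from the miR-23a/27a/24-2 precursor, was lower in spheres of every line. Its scaled log2 signal was 0.90 ± 0.65 (SD, n = 3) in adherent cells and -0.45 ± 0.70 (SD, n = 3) in spheres. The difference was -1.49 in HCC70, -1.17 in HCC1954 and -1.39 in MCF-7. The mean difference was -1.35 (SE 0.19), or 2.55-fold lower. As the single miRNA chosen in advance it fell, with an unadjusted p of 0.00115 in the limma fit, but among all 168 miRNAs it did not pass (limma adjusted p = 0.0642). The choice followed the description of this series, which may itself rest on these data. The unadjusted p is therefore not independent of them. An exact sign-flip permutation test over the 3 pairs gave a two-sided p of 0.25, the smallest that 3 pairs allow. With a mean-variance trend the adjusted p was 0.00873, and without the cell line block it was 0.975.

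**Figure D2:**
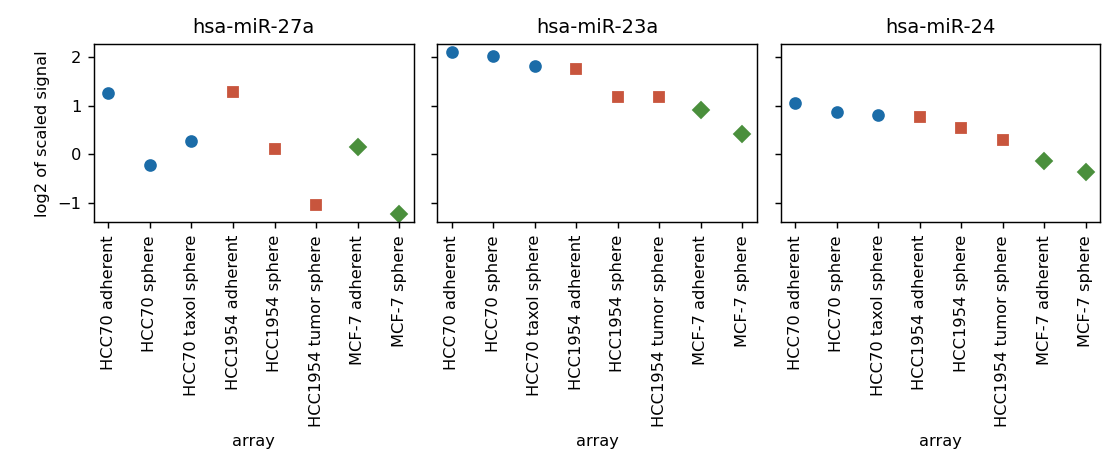
Scaled signal (log2, vertical axis) of hsa-miR-27a, hsa-miR-23a and hsa-miR-24 on each of the 8 arrays (horizontal axis), with 1 point per array and colour and shape for the cell line. For hsa-miR-27a each sphere array lies below the adherent array of its line, by 1.17 to 1.49, and for hsa-miR-23a by 0.09 to 0.57.

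Its relatives on the same and the paralogous precursor differed less. The list of miR-23/27/24 clusters had 5 tested members, of which 0 passed over all miRNAs and 1, hsa-miR-27a, passed when adjusted over the list alone (limma adjusted p = 0.00573). The list holds hsa-miR-27a and its relatives, so its tests share the limit of that choice. The paralog hsa-miR-27b had a difference of -0.60 (SE 0.21), hsa-miR-23a of -0.38 (SE 0.21), hsa-miR-24 of -0.21 (SE 0.18) and hsa-miR-23b of 0.03 (SE 0.18). As a set the list did not pass with camera (adjusted p = 0.309, and adjusted p = 0.878 with an estimated correlation). With fry, which asks only whether the members move 1 way on balance, it fell (adjusted p = 0.0177). That call was kept in 8 of 19 alternatives and lost in 11. Of those that kept it, 1, the mean-variance trend, leaves the tests of lists unchanged by construction. Those that lost it include no scaling, quantile normalization, no replicate block and leaving out any of the 3 lines.

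Of all tested miRNAs, hsa-miR-1246 and hsa-miR-630 fell in spheres. In adherent cells hsa-miR-1246, a sequence also found within the U2 small nuclear RNA, had a scaled log2 signal of -1.15 ± 0.97 (SD, n = 3). It fell by 4.14 (SE 0.29, limma adjusted p = 0.00817), in 3 of 3 lines. The signal of hsa-miR-630 was -1.95 ± 1.19 (SD, n = 3) in adherent cells, and it fell by 3.51 (SE 0.34, limma adjusted p = 0.0179), also in 3 of 3 lines. Both were detected on all 3 adherent arrays but on 1 sphere array, that of HCC1954, where they were 11.2-fold and 9.30-fold lower than in adherent cells. The other sphere arrays entered the fit at the floor of -6.16, so the sizes depend in part on that floor. In HCC70 spheres hsa-miR-1246 was at least 18.5-fold and hsa-miR-630 at least 20.2-fold lower, and in MCF-7 spheres at least 28.9-fold and at least 8.68-fold. Another RNA of low sphere signal, hsa-miR-1290, differed by -4.78 in HCC1954, was at least 6.15-fold lower in MCF-7 spheres, lay near the floor on both HCC70 arrays and did not pass (limma adjusted p = 0.292); it lay outside the rule for names and was chosen after its values were seen.

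No miRNA rose: limma called 0 higher and 2 lower at an adjusted p of 0.05, and 7 higher and 19 lower at an unadjusted p of 0.05. The median difference over the 168 miRNAs was -0.11, and it was -0.79 without scaling, -0.69 with scaling to the spike-ins, 0.01 with quantile normalization, 0.07 with the percentile over all human miRNAs and 0.12 with scaling that leaves out the tumor sphere, so every difference is relative to the scaling. With the normexp background correction the median was 0.84 and the split became 99 higher and 5 lower. Without the HCC70 or the MCF-7 pair 0 miRNAs were called, and without the HCC1954 pair 0 rose and 4 fell.

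Several further miRNAs were lower in all 3 lines without passing. The mean difference was -1.70 (SE 0.31) for hsa-miR-29b, of the miR-29 family that targets collagen and other matrix genes, -1.57 (SE 0.43) for hsa-miR-193a-3p, -1.35 (SE 0.43) for hsa-miR-141 and -1.32 (SE 0.30) for hsa-miR-101, which targets the histone methyltransferase EZH2. For hsa-miR-923_v12.0, a fragment of ribosomal RNA once listed as a miRNA, it was -1.22 (SE 0.28), for hsa-miR-30e -1.05 (SE 0.34) and for hsa-miR-301a -0.65 (SE 0.24). With normexp hsa-miR-101 (0.24), hsa-miR-30e (0.83) and hsa-miR-301a (0.10) turned positive, the latter pair also at offset 0. On the higher side, also without passing, hsa-miR-125a-5p had 0.79 (SE 0.24), hsa-miR-149 had 0.78 (SE 0.28), hsa-miR-181a had 0.76 (SE 0.42) and hsa-miR-99b had 0.72 (SE 0.26). Smaller positive values were those of hsa-miR-548c-3p (0.66), hsa-miR-197 (0.60), hsa-miR-183 (0.60), hsa-miR-574-3p (0.60), hsa-miR-1260 (0.54) and hsa-miR-22 (0.48). Their sign depends on the scaling: without it, values away from the floor shift alike by -0.85, which turns all 10 negative, and with scaling to the spike-ins by -0.75, which turns 7 negative.

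**Figure D3:**
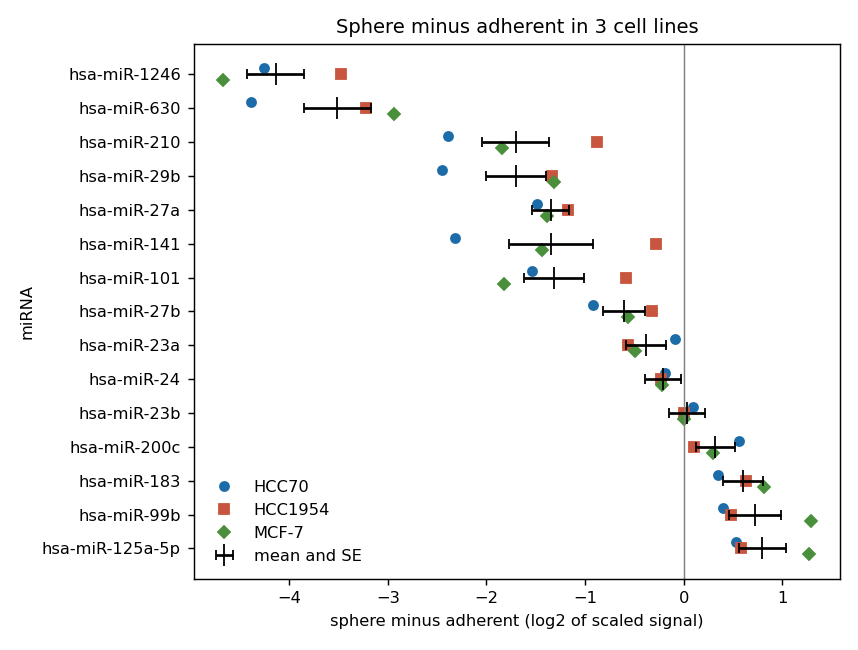
Sphere minus adherent difference (log2 of scaled signal, horizontal axis) of 15 miRNAs (vertical axis), with coloured points for the 3 cell lines and black bars for the mean and its standard error in the fit. Of these, hsa-miR-1246 (mean -4.14) and hsa-miR-630 (mean -3.51) passed the test over all miRNAs, and hsa-miR-27a (mean -1.35) lies between -1.49 and -1.17 in the 3 lines.

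Groups of related miRNAs gave few calls. Among the lists with at least 3 tested members, camera called 0 of 10 with the preset and with the estimated correlation, and fry called the miR-23/27/24 clusters alone. In the miR-29 family 0 of 3 members passed over all miRNAs, while hsa-miR-29b passed when adjusted over the list alone (limma adjusted p = 0.00934), beside hsa-miR-29c with -0.40 and hsa-miR-29a with -0.25. The miR-200 family and miR-205, which keep cells epithelial, had 0 of 6 members passing on either adjustment, from -1.35 for hsa-miR-141 and -0.46 for hsa-miR-200a to 0.50 for hsa-miR-200b. In HCC1954, hsa-miR-200a lay at the floor on both arrays, which sets its difference there to 0, and hsa-miR-200b on the adherent array. In the cluster of hsa-miR-183, hsa-miR-96 and hsa-miR-182 none passed on either adjustment, with 0.60 for hsa-miR-183, 0.39 for hsa-miR-182, which lay at the floor on both HCC70 arrays and the HCC1954 adherent array, and -0.33 for hsa-miR-96.

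The let-7 family, known for opposing the stem cell state, had 0 of 9 members passing on either adjustment, with -0.42 for hsa-let-7i, -0.21 for hsa-let-7f and 0.25 for hsa-let-7e. For the proliferation-linked miR-17-92 and paralog clusters it was 0 of 11, with -0.56 for hsa-miR-19a, -0.52 for hsa-miR-20b and -0.50 for hsa-miR-106b. The miR-15/16 family had 0 of 6 and a median of -0.53, with line medians of -0.10 in HCC70, 0.06 in HCC1954 and -0.56 in MCF-7. The values of hsa-miR-497 (-0.63) and hsa-miR-195 (-0.53) came mostly from MCF-7, with -1.88 and -1.40 there and at or near the floor elsewhere, and hsa-miR-15a had -0.54. The miR-30 family had 0 of 6 and a median of -0.10. None of the 3 tested p53-responsive miRNAs passed (hsa-miR-34a -0.08), nor did any of the 4 invasion-associated ones (hsa-miR-21 -0.54, hsa-miR-103 0.38, hsa-miR-107 0.29). Counts adjusted over the list alone were 0 in each of these lists as well.

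The hypoxia-induced hsa-miR-210, the single tested member of its list, differed by -1.70 (SE 0.34), with the HCC70 sphere array at the floor. It was at least 5.08-fold lower in HCC70 spheres and differed by -0.88 in HCC1954 and -1.84 in MCF-7. It did not pass over all miRNAs (limma adjusted p = 0.144) and passed when adjusted over the list alone (limma adjusted p = 0.00491), which for 1 member is no adjustment. Of 9 pluripotency-associated miRNAs 0 were detected on enough arrays to be tested. Markers of other cell types were low: 0 of 6 stromal and 0 of 7 blood cell miRNAs were detected on any array, and the endothelial hsa-miR-126 was detected on 3 of 6 arrays with a difference of 0.10 (SE 0.19).

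Between the cell lines, the F test called 65 of 168 miRNAs. Without a replicate within a line, the p-values for lines measure how alike line differences were in adherent cells and spheres, beside the prior. They do not measure variation between independent cultures of a line. Against the mean of the other lines, 19 miRNAs were higher and 15 lower in HCC70, 20 higher and 12 lower in HCC1954, and 31 higher and 38 lower in MCF-7. The number called by the F test was 14 without scaling, 17 with spike-in scaling, 41 with quantile normalization, and 137 or 0 with normexp at an offset of 50 or 0. The split by direction also depended on the scaling, with 78 higher and 16 lower in MCF-7 and 12 higher and 35 lower in HCC1954 when the percentile was taken over all human miRNAs, and 7 higher and 97 lower in MCF-7 and 123 higher and 3 lower in HCC1954 with normexp.

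HCC1954 stood apart by very low hsa-miR-200b, hsa-miR-200a and hsa-miR-429, neighbours in 1 cluster that repress the mesenchymal regulators ZEB1 and ZEB2. The mean scaled log2 signal of hsa-miR-200b was 1.67 in HCC70, 0.45 in MCF-7 and -5.96 in HCC1954, where it fell short of the others by -7.02 (SE 0.20, limma adjusted p = 0.000117), a size that depends on the floor, since it was detected on 1 of 2 HCC1954 arrays. On both HCC1954 arrays hsa-miR-200a and hsa-miR-429 were not well above background, where the fit, with both at the floor, gave differences of -5.78 and -4.40 (limma adjusted p = 0.0005 for each). Against the lowest detected signal of these arrays, which lies under the floor, they were at least 74.2-fold and at least 28.5-fold lower than in the other lines. With MCF-7 at the floor, HCC1954 was in turn highest in hsa-miR-205 and hsa-miR-221, by 4.44 (SE 0.23, limma adjusted p = 0.0005) and 4.53 (SE 0.34, limma adjusted p = 0.00192) over the mean of the others. It was also higher in hsa-miR-452 (2.26), again with MCF-7 at the floor.

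MCF-7 was highest in hsa-miR-342-3p, a miRNA tied to estrogen receptor-positive tumors, by 6.12 (SE 0.36, limma adjusted p = 0.000853), with 1 of the 4 other arrays at the floor. It was also higher in hsa-miR-301a (2.75), hsa-miR-454 (2.06) and hsa-miR-625 (2.27), the last with both HCC70 arrays at the floor. On neither MCF-7 array were hsa-miR-224, hsa-miR-205, hsa-miR-31 and hsa-miR-221 well above background, where the fit, at the floor, gave differences of -5.58, -4.98, -4.07 and -4.04 (limma adjusted p from 0.000365 to 0.00277). Against the lowest detected signal they were lower there than in the other lines by at least 85.0-fold, 56.2-fold, 29.9-fold and 29.3-fold. HCC70 was higher in hsa-miR-200b (4.43), hsa-miR-224 (2.60), hsa-miR-31 (2.19) and hsa-miR-203 (1.87), in each case over a mean that includes a line near the floor. It was lower in hsa-miR-98 (-1.67). The levels of hsa-miR-224 in HCC70 and HCC1954 were -0.70 and -0.45, and those of hsa-miR-31 were -1.98 and -2.19. HCC1954 was thus also higher in hsa-miR-224 (2.98) and hsa-miR-31 (1.88) than the mean of the others. MCF-7 was also lower in hsa-miR-27a, by -1.15 (SE 0.20, limma adjusted p = 0.0162), a value outside the rule for names.

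**Figure D4:**
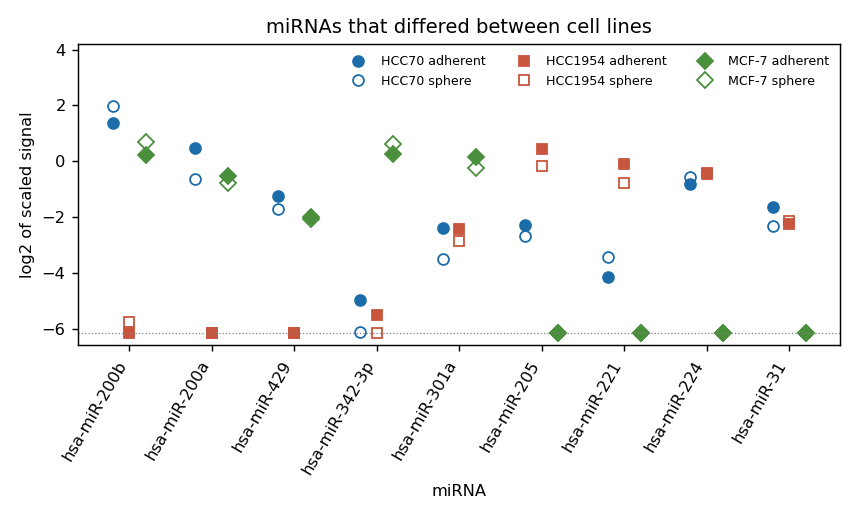
Scaled signal (log2, vertical axis) of 9 miRNAs (horizontal axis) on the 6 adherent (filled) and sphere (open) arrays, with colour and shape for the cell line and a dotted line at the floor of -6.16. Both HCC1954 arrays lie at or near the floor for hsa-miR-200b, hsa-miR-200a and hsa-miR-429, and both MCF-7 arrays at the floor for hsa-miR-205, hsa-miR-221, hsa-miR-224 and hsa-miR-31.

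Within each line, spheres and adherent cells could be set side by side without a replicate. The counts cover only miRNAs detected on both arrays. Detected on the adherent array alone were 71 in HCC70, 11 in HCC1954 and 54 in MCF-7, against 1, 26 and 1 on the sphere array alone. In HCC70, 2 of 122 miRNAs detected on both arrays were higher in spheres by at least 1 on the log2 scale and 15 were lower. The largest negative values were those of hsa-miR-29b (-2.45, spot SE 0.06), hsa-miR-141 (-2.32), hsa-miR-193a-3p (-2.27) and hsa-miR-30e (-1.76), and the positive ones those of hsa-miR-29b-1* (1.15) and hsa-miR-940 (1.11). In HCC1954, 6 of 140 were higher and 7 lower, led by hsa-miR-1915 (2.43) and hsa-miR-149 (1.29) and by hsa-miR-1290 (-4.78), hsa-miR-1246 (-3.48) and hsa-miR-630 (-3.22). In MCF-7, 7 of 137 were higher, among them hsa-miR-181a (1.91), hsa-miR-375 (1.89) and hsa-miR-181b (1.81), and 14 were lower, among them hsa-miR-193a-3p (-2.08), hsa-miR-497 (-1.88), hsa-miR-210 (-1.84) and hsa-miR-101 (-1.82). The median of the miR-17-92 clusters was -0.52 in MCF-7, at percentile 0.45 of random lists, -0.37 in HCC1954 (percentile 3.92) and -0.02 in HCC70 (percentile 83.0). Members of these clusters can move together (estimated correlation 0.40 in the fit), which random lists do not take up, so the percentiles are descriptive. Without scaling the counts of miRNAs past 1 were 99 lower in HCC70 and 110 lower in MCF-7, with 0 higher in either, and 18 higher and 4 lower in HCC1954. With normexp 79 were higher and 1 lower in HCC1954.

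Across miRNAs, the sphere differences of the lines were positively correlated, with no array shared between the sides. Pearson's r was 0.571 (Spearman's rho 0.424) for HCC70 with MCF-7, 0.425 (0.351) for HCC1954 with MCF-7 and 0.274 (0.101) for HCC70 with HCC1954, over 168 miRNAs. The share of these miRNAs with the same sign in both lines of a pair lay between 52.4% and 57.1%. Over the 96 miRNAs detected on all 6 arrays it lay between 63.5% and 69.8%. The miRNAs are not independent replicates, so these values are descriptive. In HCC70 and MCF-7, the pair with the highest r, the sphere array was dimmer than the adherent one (75th percentile 773 against 2225 and 1082 against 3115). A shared effect of array signal therefore cannot be told apart for that pair.

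Taxol spheres and untreated spheres of HCC70 had similar levels. Of 120 miRNAs detected on both arrays, 1, hsa-miR-29b, was higher with taxol by at least 1 (1.05, spot SE 0.05), and 0 were lower. The difference was 0.50 for hsa-miR-27a, which lay above 88.3% of the miRNAs. Its level with taxol was 0.27, between 1.26 in adherent cells and -0.23 in spheres. Of the untreated and taxol sphere arrays, 19 miRNAs were detected with taxol alone and 3 without it alone. The former included hsa-miR-146a, at least 4.33-fold higher, and hsa-miR-939, at least 3.21-fold higher. The miR-29 family had a median of 0.56 (percentile 95.6 of random lists) and the miR-17-92 clusters one of 0.26 (percentile 91.1). Against adherent cells the median of the latter was 0.23 (percentile 99.84), opposite in sign to that of MCF-7 spheres. Against HCC70 adherent cells, 1 of 137 miRNAs was higher in taxol spheres (hsa-miR-940, 1.10) and 10 were lower, led by hsa-miR-1246 (-3.84), hsa-miR-33a (-1.93) and hsa-miR-193a-3p (-1.73). Without scaling 115 were lower and 0 higher, and with spike-in scaling 89 and 0. This last comparison shares its adherent array with that of untreated HCC70 spheres. With 1 array on each side none of these differences could be tested, and the percentiles are descriptive.

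The HCC1954 tumor sphere had the lowest hsa-miR-27a level of that line, -1.05, against 0.12 in spheres and 1.29 in adherent cells. Against adherent cells hsa-miR-27a differed by -2.34 (spot SE 0.05), or 5.08-fold, and against spheres by -1.17. Of 68 miRNAs detected on both arrays, 19 were higher than in adherent cells by at least 1 and 13 lower, while 83 were detected in adherent cells alone and 0 in the tumor sphere alone. Without scaling and with spike-in scaling 56 were lower and 0 higher, and with the percentile over all human miRNAs 34 were lower and 5 higher. Lower ones included hsa-miR-141 (-2.67), hsa-miR-1246 (-2.41), hsa-miR-27b (-1.76), hsa-miR-106b (-1.74), hsa-miR-19b (-1.52) and hsa-miR-20a (-1.37), and higher ones hsa-miR-1915 (3.42), hsa-miR-940 (3.17), hsa-miR-548c-3p (3.01), hsa-miR-638 (2.80) and hsa-miR-494 (2.35). In adherent cells alone hsa-miR-29b was well above background, so that it was at least 7.42-fold lower in the tumor sphere. The miR-23/27/24 clusters had a median of -0.56 (percentile 12.1 of random lists), the miR-17-92 clusters of -1.05 (percentile 9.44) and the let-7 family of 0.01 (percentile 78.3).

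Against HCC1954 spheres, 19 of 68 miRNAs were higher in the tumor sphere and 7 lower, while 98 were detected in spheres alone and 0 in the tumor sphere alone. The counts thus leave out miRNAs too dim to be detected on the tumor sphere array. The lower ones were hsa-miR-141 (-2.39), hsa-miR-106b (-1.57), hsa-miR-27b (-1.43), hsa-miR-96 (-1.39), hsa-miR-15a (-1.28), hsa-miR-27a (-1.17) and hsa-miR-19b (-1.07). Higher ones included hsa-miR-638 (2.83), hsa-miR-548c-3p (2.77), hsa-miR-923_v12.0 (2.62) and hsa-miR-630 (2.16). Of the 15 stromal, endothelial and blood cell miRNAs 0 were detected on the tumor sphere array. That array's 75th percentile was the lowest, and without scaling 65 miRNAs were lower by at least 1 than in spheres and 0 higher.

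Across the 68 miRNAs detected in the tumor sphere, its difference from HCC1954 adherent cells correlated with the mean sphere difference of HCC70 and MCF-7 (r = 0.287, rho = 0.369). The taxol difference in HCC70 correlated negatively with the mean sphere difference of HCC1954 and MCF-7 over 168 miRNAs (r = -0.313, rho = -0.352). Neither pair shares an array, and with miRNAs detected on all 6 arrays alone the values were 0.597 over 56 and -0.528 over 96 miRNAs. The tumor sphere array was the dimmest, so a shared effect of array signal cannot be told apart there either.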

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

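All tests of explanations in this part were chosen after the results they bear on had been seen.

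The change in spheres had opposite signs between lines for several named miRNAs. Those given here had a size of at least 0.3 on both sides. These differences between lines were not tested. For hsa-miR-29a it was -0.73 in HCC70 and -0.36 in HCC1954 but 0.34 in MCF-7. For hsa-miR-34a it was -0.87 in HCC70 but 0.54 in HCC1954. For hsa-miR-34b*, detected on 4 of 6 arrays, it was -0.93 in HCC70, with the sphere array near the floor, but 0.32 in HCC1954. Data outside the comparisons also held signal. At most 3 of the 88 viral miRNAs were well above background on an array. In the authors' table of processed values, 229 rows of the MCF-7 adherent column and 169 rows of the MCF-7 sphere column equalled the HCC70 signal times 1 factor, within 2%.

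Technical accounts of the lower level of hsa-miR-27a in spheres could be weighed only in part. Lower miRNA signal on sphere arrays would move miRNAs of like brightness with it. Relative to the median of the 20 nearest in signal, however, hsa-miR-27a lay at -1.40 (SD 0.20 over 3 lines). It was chosen from the series description, which may rest on these data, so this distance is not independent of the choice. Matching on brightness also cannot exclude a loss that depends on another property of a miRNA. Signal shared with hsa-miR-27b would not exceed the change of that paralog, yet the difference between them was -0.75 (SD 0.15). The difference to hsa-miR-23a, of the same precursor, was -0.97 (SD 0.40). Signal that hsa-miR-23a may share with its paralog hsa-miR-23b was not tested. An equal change of the whole miR-23a/27a/24-2 precursor therefore stays open. The medium stays open and cannot be told apart from the culture, since 0 adherent arrays came from cells grown without serum.

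Splits of the arrays are too few to set the count of 2 called miRNAs against chance, since 6 arrays make 10 splits into 3 and 3. In simulated data without change, with noise from the fit's own model and no floor, the fit called a mean of 0.12 miRNAs. The real split, 1 of the 10, called 2 miRNAs and the highest other split 0. Among the splits that, like the real one, part all 3 lines, the highest other number at an unadjusted p of 0.05 was 8, against 26. The remaining splits part 1 line and keep the others whole. With the line as a block, they rest on the arrays of that 1 line.

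The fall of hsa-miR-1246 and hsa-miR-630 also exceeded that of miRNAs of like brightness, by a mean of -3.79 (SD 0.41 over 3 lines). Both were picked for their fall, and on the dim HCC70 and MCF-7 sphere arrays both lay at the floor. The distance there cannot exclude a loss that depends on signal. In HCC1954, both were detected in spheres, whose array was brighter than the adherent one (75th percentile 1217 against 864). The distances there were -3.57 for hsa-miR-1246 and -3.12 for hsa-miR-630. A general excess of RNA fragments in adherent cells would lower the 6 tRNA-derived fragments and the ribosomal fragment hsa-miR-923_v12.0 that the array lists as miRNAs. The latter lay at -1.30 in HCC70, -0.62 in HCC1954 and -1.73 in MCF-7 without passing the test. For the tRNA-derived fragments the median change was 0.37 (SD 0.53 over 3 lines), 0.81 in HCC70, -0.22 in HCC1954 and 0.51 in MCF-7. These go apart, so an excess of fragments of some longer RNAs stays open. A source specific to these RNAs, such as a change of the U2 small nuclear RNA, was not tested, and the medium again cannot be separated from the culture.

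The tumor sphere array was dim, with a 75th percentile that differed from the median of the other 7 by -3.12 on the log2 scale. Poor hybridization or scanning would dim the spike-in controls alike, but they differed by -0.0905 (SD 0.14 over the others). Of the 15 markers of stromal, endothelial and blood cells, which host cell RNA could bring, 0 were detected. Their highest scaled signal was 0.0607, under the lowest detected signal of 0.114. With 68 human miRNAs detected on this dim array, their absence speaks only against amounts that would lift a marker over that limit. Smaller amounts of host cell RNA stay open. A lower miRNA content of the RNA, RNA losses before labelling, or a failure of labelling stay open, since the sources do not say whether the spike-ins were added before labelling, as does the origin of the culture from a tumor.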

How the results depend on the processing

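Every alternative kept the direction of hsa-miR-27a: over 19 of them its difference ranged from -2.20 to -1.08, the unadjusted p from 3.96e-05 to 0.0421 and the adjusted p from 0.000704 to 0.975, with 2 below 0.05. Spike-in scaling, scaling without the tumor sphere and normexp with offset 0 were chosen after seeing the data. Signal over background limits what can be said: 96 of 168 tested miRNAs were detected on all 6 arrays. The cause of a difference was not tested unless given. The table of the authors' values was not run for the fits, because its HCC70 and MCF-7 columns could not be matched to their arrays.

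The 2 lower miRNAs became 1 with quantile normalization and with the floor at the 10th percentile, 5 without scaling, with spike-in scaling and with normexp, and 0 with normexp at offset 0. They became 0 with miRNAs detected on all 6 arrays, where the filter removes both, and 0 with those detected on at least 1 array and with no replicate block. Leaving out 1 cell line pair gave from 0 to 4. Without the block the fit called 0 miRNAs at an unadjusted count of 6. The 0 higher miRNAs became 99 with normexp. The 65 that differed between cell lines became 41 with quantile normalization, 14 without scaling, 17 with spike-in scaling, 137 with normexp, 0 at its offset 0 and 43 with miRNAs detected on at least 1 array. The 0 called lists became 2 with normexp, 3 at its offset 0, 1 with miRNAs detected on at least 1 array and 1 with fry. With an estimated correlation camera called 0 lists in each of these settings.

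Counts of miRNAs past 1 also moved, given here for HCC70, HCC1954 and MCF-7 spheres against adherent cells (17, 13 and 21), taxol spheres against spheres (1) and adherent cells (11), and the tumor sphere against spheres (26) and adherent cells (32). Without scaling they were 99, 22, 110, 2, 115, 65 and 56. With spike-in scaling they were 89, 20, 96, 3, 89, 65 and 56. At a size of 1.5, which by construction keeps fewer, they were 5, 5, 12, 0, 3, 9 and 19. With normexp the 1st, 2nd, 4th and 6th became 26, 80, 0 and 2, and at offset 0 the 2nd, 4th and 6th became 95, 0 and 11. Quantile normalization gave 8 for HCC1954 and 3 for taxol against spheres. Scaling without the tumor sphere gave 28 for HCC70 and 0 for taxol against spheres. The latter was 3 with the total miRNA signal and 2 with the brightest probe, which gave 7 for taxol against adherent cells. With the authors' table all 68 were higher in the tumor sphere in both comparisons, since that column is divided by the value of undetected miRNAs.

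Correlations moved too. For HCC70 with MCF-7 r was 0.407 without scaling, 0.420 with spike-in scaling and 0.722 with normexp, which also gave 0.706 for HCC70 with HCC1954, 0.612 for HCC1954 with MCF-7, 0.690 for the tumor sphere and -0.460 for taxol. With miRNAs detected on all 6 arrays the last pair were 0.597 and -0.528.

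Leaving out the scaling shifts miRNAs away from the floor alike by -0.85, and spike-in scaling by -0.75, so the reversals under them follow by construction and are not specific to the miRNA. Without scaling, direction reversed for hsa-miR-125a-5p (-0.0574), hsa-miR-149 (-0.0757), hsa-miR-181a (-0.10), hsa-miR-99b (-0.13), hsa-miR-548c-3p (-0.19), hsa-miR-197 (-0.25), hsa-miR-183 (-0.25), hsa-miR-574-3p (-0.26), hsa-miR-1260 (-0.31) and hsa-miR-22 (-0.37). With spike-in scaling it did for hsa-miR-99b (-0.0275), hsa-miR-548c-3p (-0.0908), hsa-miR-197 (-0.15), hsa-miR-183 (-0.15), hsa-miR-574-3p (-0.15), hsa-miR-1260 (-0.21) and hsa-miR-22 (-0.27). With normexp it did for hsa-miR-101 (0.24), hsa-miR-30e (0.83) and hsa-miR-301a (0.10), and at offset 0 for hsa-miR-30e (0.69) and hsa-miR-301a (0.0567). Of the other values of single named miRNAs, 308 kept direction and side of the threshold, 16 passed it newly and 13 no longer passed.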

Other observations

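The test in the last paragraph was chosen after the values had been seen. The low hsa-miR-200b, hsa-miR-200a and hsa-miR-429 signal of HCC1954 did not extend to the other cluster of the family. The mean scaled log2 signal of hsa-miR-200c was 1.37 in HCC1954, 0.64 in HCC70 and 0.82 in MCF-7, and that of hsa-miR-141 was -0.33, -1.55 and -0.58, and neither passed the F test (limma adjusted p = 0.125 and 0.208). Within that other cluster the sphere values of the members differed, without a test of the difference and with neither passing: hsa-miR-141 differed by -2.32 in HCC70, -0.28 in HCC1954 and -1.44 in MCF-7, and hsa-miR-200c by 0.56, 0.11 and 0.29. Before scaling, the sphere arrays of HCC70 and MCF-7 were dimmer than their adherent arrays (75th percentile 773 against 2225 and 1082 against 3115). Whether array signal bears on the values of hsa-miR-141 was not tested. In the HCC1954 tumor sphere the level of hsa-miR-141 was -2.86 and that of hsa-miR-200c 2.12.

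The tRNA-derived fragments listed as miRNAs (hsa-miR-720, hsa-miR-1274a, hsa-miR-1274b, hsa-miR-1260, hsa-miR-1280 and hsa-miR-1308, a list made after the data were seen) had a median difference of 0.81 in HCC70 spheres, at percentile 99.97 of random lists, 0.51 in MCF-7 (percentile 96.9) and -0.22 in HCC1954 (percentile 30.0). With taxol their median was -0.27 relative to HCC70 spheres (percentile 1.50). None of the 6 passed the test over all miRNAs or when adjusted over the list alone. The percentiles are descriptive, since random lists do not take up that members can move together.

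A hypothesis was that neighbouring miRNA genes, which may share a precursor transcript, changed alike in spheres. Of 168 tested miRNAs 134 matched 1 gene in RefSeq, 20 matched several and 14 none, which left 48 pairs of mature miRNAs from 32 pairs of genes within 10000 bases, so some gene pairs count more than once. The mean absolute difference in change within pairs was 0.46 on the log2 scale, against 0.54 after permuting the changes among the members (one-sided permutation p = 0.0927 over 10000 permutations), which leaves the hypothesis open. The widest gaps were those of hsa-miR-141 and hsa-miR-200c (1.67), hsa-miR-141* and hsa-miR-200c (1.22), and hsa-miR-23a and hsa-miR-27a (0.97).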
